A study of Mus musculus with 3 samples.

How the data were processed

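RNA of 3 epithelial lineages of the mouse stomach was measured on Affymetrix Mouse Genome 430 2.0 arrays, with 1 array each for parietal, zymogenic and pit cells. Per the labels' design text, cells were collected by laser-capture microdissection with a spot of 7.5 µm. Parietal cells were recognised by binding of the lectin DBA and by autofluorescence and were taken singly from the pit zone. Pit cells, positive for E-cadherin and negative for DBA, followed from the same gastric units, from a layer 2 to 3 cells thick at the apex. Zymogenic cells, positive for E-cadherin and negative for the lectins GSII and DBA, came from the base of units on other slides, once parietal cells there had been removed. Each lineage gave 3000 to 5000 cells from 4 to 5 mice, and RNA was pooled over mice and dissections to 20 ng. The pool was amplified with the RiboAmp HS kit and an Enzo kit and labelled with biotin. The design text speaks of total RNA while the molecule label reads nuclear RNA, and the files do not settle which holds.

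The values are intensities on a linear scale, 1 per probe set and array, as the authors deposited them. The method that summarised probes into probe sets, the background correction and the scaling between arrays are not given in the sources used here. The values run from 0 to 12079 on the parietal array, 11325 on the zymogenic array and 11141 on the pit array, with medians of 4.50, 4.81 and 4.64. No further scaling was applied in the main setting. Amplification of small samples can lose the 5′ ends of transcripts, so a probe set far from the 3′ end can read low for a gene that is present, and the 3′ to 5′ ratios of the control transcripts are reported for that reason.

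Of 45101 probe sets, 64 are controls and 35890 are in the platform's gene table. Of these, 34958 name 1 gene and 932 name several, and the latter were left out of every named result. A further 9160 probe sets that are not controls are not in the table and are unnamed here. Symbols of 34754 probe sets were matched through the gene identifier to a RefSeq gene table of the assembly GRCm38, which served for names alone, and no coordinates are given because the files name no genome build. Each of the 18194 genes was represented by its probe set of highest mean over the 3 arrays.

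A detection floor of 23.3 was set as the highest, over the 3 arrays, of the 95th percentile of 80 probe sets for olfactory and vomeronasal receptors, which stand for genes that the stomach should not express. Values under the floor were raised to it before log2 was taken. A fold against values at the floor is a lower bound and is given as at least that fold. With 1 array per lineage there is no replicate error, no test between lineages and no p-value. The number of arrays limits the precision of every value. As a description of measurement scatter alone, the log2 ratios between arrays from different probe sets of 1 gene had an SD of 0.479, which corresponds to 0.338 per array, over 785 combinations of gene and array pair above the floor on both arrays.

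A gene counted as enriched in a lineage when its value was at least 4-fold above the floored values of both other arrays, and pairs of lineages were compared by the number of genes at least 4-fold apart each way. For each of 31 gene lists, 14 of cell type markers and 17 of functions, the median log2 ratio of a lineage to the mean log2 of the other 2 was taken over members above the floor on at least 1 array. Its percentile is among 10000 random lists of the same size matched on mean expression in 20 bins, and the interval over members comes from 2000 bootstrap draws. Members at least 2-fold higher or lower than on both other arrays were counted. Named genes were chosen by rule. For each lineage these are the 12 with the largest ratio to the higher of the other arrays among genes above the floor there and on another array, the 12 brightest of those with both other arrays at or under the floor and at least 4-fold above it, and the 5 lowest among genes above the floor on all 3 arrays. For each pair of lineages they are the 5 largest ratios each way among genes above the floor on both arrays, and list members serve as examples. The lists, the rule, the floor and most of the alternatives were fixed before the data were examined.

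Alternatives were quantile normalization, scaling to 1 median, floors at the 90th and 99th percentile, the floor as a pseudocount, the mean over all probe sets of a gene, probe sets whose names mark them as specific to 1 transcript, and thresholds of 2-fold and 8-fold. Scaling to the BioB and BioC hybridisation controls and leaving out 1 array were added after the data were seen. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated data with 200 changed genes among 18194 and a noise SD of 0.338. The changed genes were drawn from those with a mean more than 2-fold above the floor, and the noise SD came from probe sets above it. The shares recovered and the number of unchanged genes called therefore do not cover genes near the floor, where scatter was not measured. At 8-fold, 98.5% of changed genes were recovered for the parietal array, 98% for the zymogenic and 97.5% for the pit array. At 4-fold, the threshold itself, these shares were 31.5%, 37.5% and 32.5%, and 0 unchanged genes were called. Of lists of 20 genes raised 2-fold on the simulated pit array, 20 of 20 were placed above the 97.5th percentile, and 5 of 100 unchanged lists fell outside the 2.5th to 97.5th percentile.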

Results

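The lineages profiled were parietal cells, which secrete acid, zymogenic (chief) cells, which secrete pepsinogen and other digestive proteins, and pit cells, the mucous cells that line the upper part of each gastric unit. Each was measured on 1 array of pooled RNA, so that every difference given here describes these 3 arrays and has no replicate check. Parietal and pit cells came from the same gastric units. Zymogenic cells came from other slides, and slide and lineage cannot be told apart for that array.

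Of 18194 genes, 4138 exceeded the detection floor of 23.3 on at least 1 array and 1186 on all 3. The parietal array had 2809 genes above the floor, the zymogenic array 2285 and the pit array 2616. The 10 brightest genes held 13.0%, 16.7% and 11.2% of the summed gene signal on the parietal, zymogenic and pit arrays. The 3′ over 5′ ratio of the beta-actin control, from unfloored values, was 26.1 on the parietal array, 14.7 on the zymogenic array and 9.04 on the pit array, and that of Gapdh was 8.84, 3.88 and 6.66. The 5′ value was under the floor for actin on the zymogenic array (5.23) and for Gapdh on all 3 (22.4, 12.3 and 14.0). The parietal 5′ actin value, 23.7, was close to it. These ratios are therefore imprecise and do not order the arrays by loss of 5′ ends. The BioB and BioC hybridisation controls averaged 299.8 on the parietal array against 700.3 and 701 on the zymogenic and pit arrays. The Cre control did not show that offset, at 9453 on the parietal, 9117 on the zymogenic and 9268 on the pit array. Scaling to BioB and BioC thus rests on an offset that Cre does not show. The Cre values lie near the array maxima of 12079, 11325 and 11141, where an offset could be hidden. Cre therefore cannot decide whether the offset holds for other probe sets. Over the 1186 genes, the median log2 difference was 0.29 for parietal minus pit, -0.21 for zymogenic minus pit and -0.64 for zymogenic minus parietal. Quantile normalization brought these to 0.054, 0.048 and -0.080.

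Genes known to mark the 3 lineages were examined first, as a check on the collections. Atp4b, the beta subunit of the gastric proton pump, stood at 4402 on the parietal array, 793 on the zymogenic array and 102 on the pit array. Atp4a, the catalytic subunit, did not separate parietal from zymogenic cells, with 214, 261 and 12.5. The zymogenic array held the highest values of Pgc (pepsinogen C), at 4593 against 217 and 9.88, and of Cblif (gastric intrinsic factor), at 558 against 2.62 and 3.18. Muc5ac, the surface mucin, was at 1225 on the pit array, 425 on the parietal array and 14.5 on the zymogenic array. Gkn1 and Gkn2, gastrokines secreted by surface mucous cells, were higher on the parietal array (10493 and 7987) than on the pit array (8307 and 2723) and were at 12.5 and 8.28 on the zymogenic array.

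As a group, zymogenic markers were higher on their own array, where 6 of 10 were at least 2-fold above both other arrays, with a median log2 ratio of 1.66 (95% interval over members 0.10 to 4.59, 100th percentile of matched lists). Pit markers had a median of 1.57 on the pit array (99.8th percentile, 4 of 13 higher than both), 1.33 on the parietal array (99.5th percentile, 3 of 13) and -2.64 on the zymogenic array (0.07th percentile, 9 of 13 lower than both). Parietal markers did not stand apart on the parietal array, with a median of 0.45 at the 68th percentile. Only Atp4b, Car2 and Clic6 of 13 were 2-fold above both other arrays, and the median was -0.074 with the arrays scaled to 1 median and 1.22 with the BioB and BioC controls. With those controls the pit list had a median of 0.87 on the pit and 2.49 on the parietal array. Without the zymogenic array, the pit list on the pit array had a median of 0.23 at the 92.6th percentile. It lay at the 96.4th percentile there with transcript-specific probe sets, and at the 95.45th on the parietal array with the mean over all probe sets of a gene. With the floor at the 99th percentile of the receptor probe sets (868), which left 81 genes, every one of the 16 medians outside the central 95% of matched lists that could still be taken, over all lists and arrays, came to lie inside it.

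**Figure D1:**
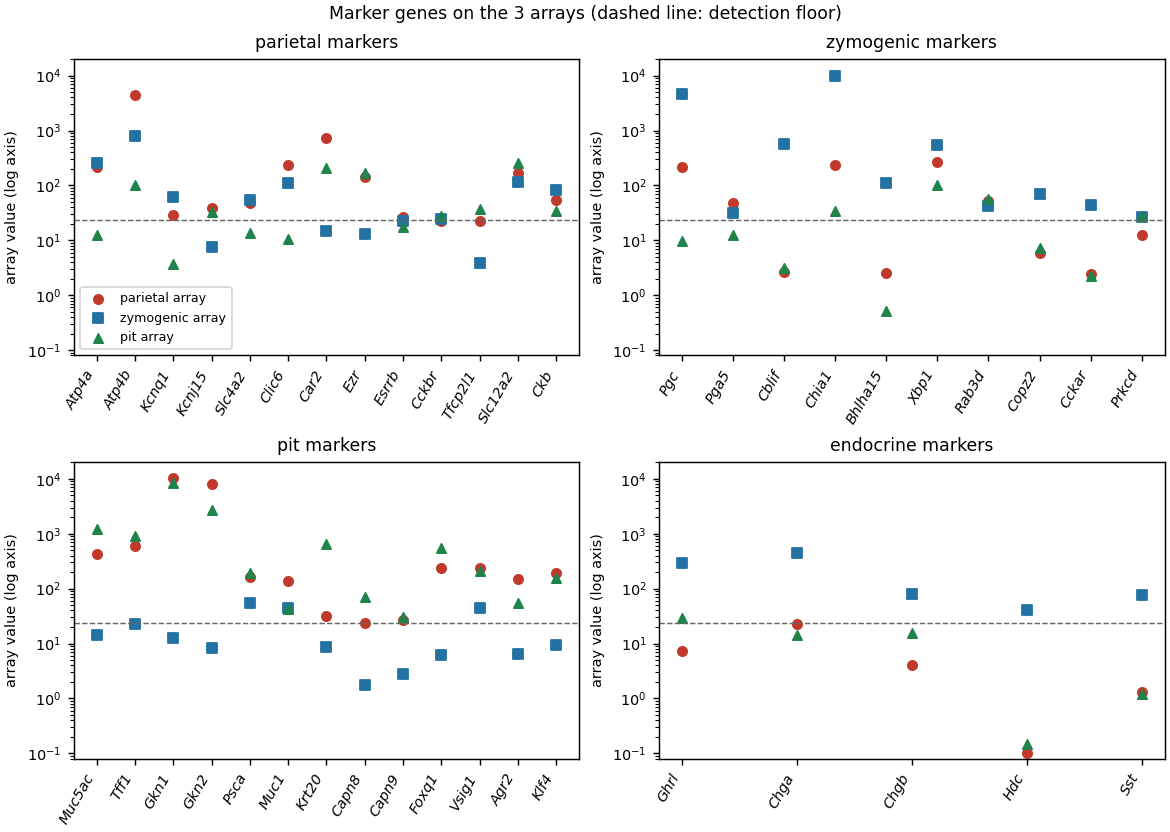
Values of parietal, zymogenic, pit and endocrine marker genes above the floor on at least 1 array (log axis, array value) on the parietal (circles), zymogenic (squares) and pit (triangles) arrays, with the floor of 23.3 as a dashed line and values under 0.1 drawn at 0.1. Pit markers such as Gkn1 lie high on both the parietal and the pit array, while Pgc, Cblif and Chga are highest on the zymogenic array.

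The parietal array was compared with the other 2 for genes that were higher or lower there. As pit markers stood apart on that array and parietal markers did not, such genes cannot be assigned to acid-secreting cells alone. Among genes also measured elsewhere, Irf7, a transcription factor of the interferon response, had the largest ratio (762, 18.5-fold above the pit array). It was followed by Lgals2, a galectin (657, 15.6-fold), Mt1, a metallothionein (881, 11.98-fold), Hspb9 and Oas1a, an antiviral oligoadenylate synthetase (539, 9.07-fold), then Ifi35, Ifi27l2b, B2m, Nfe2l2, Rpl7a, Atp4b and Clu at 5.55-fold to 7.70-fold. Genes at or below the floor on both other arrays included Ifit1bl1 (474, at least 20.4-fold), Entpd7, Sgk1, Socs7, the interferon-inducible GTPase Igtp (208, at least 8.96-fold), Dnaja1, Il33, the alcohol dehydrogenases Adh7 and Adh6a, Oasl2 and Hspa1b. The brightest was Pnn, at 9778 and at least 420-fold, but its other probe sets were under the floor on every array. Socs7, Dnaja1 and Adh7 each had 1 further probe set above the floor that was not 2-fold higher, while that of Hspa1b was. Among genes above the floor on all 3 arrays, the lowest relative to both others were Samt3, Rassf1, Tex43, Tra2a and Mettl17, at most 2.96-fold lower, with no further probe set that was also 2-fold lower.

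Genes of oxidative phosphorylation, which code for the respiratory chain and ATP synthase of mitochondria, were higher on the parietal array. Of 71 members, 20 were at least 2-fold above both other arrays and 0 at least 2-fold below, with Ndufv2 (259.9 against 70.6 and 68.1), Atp5g3 (263 against 71.7 and 66.6) and Uqcrc2 (254 against 82.1 and 72.2) among them. The median log2 ratio was 0.99 (0.79 to 1.17, 100th percentile), and 0.53 after quantile normalization, 0.49 with 1 median and 2.17 with the BioB and BioC controls. Citric acid cycle genes had a median of 1.11 (99.6th percentile, and 97.15th with transcript-specific probe sets), with Idh3b, Suclg1, Fh1 and Mdh2 of 12 higher than both, and fatty acid oxidation genes one of 0.83 (99.3rd percentile), with Acaa2, Decr1, Acadl and Etfb of 13. After quantile normalization these medians were 0.63 and 0.41, and with the BioB and BioC controls 2.01 and 1.88. Ribosomal protein genes were also higher, by a median of 1.24 (99.9th percentile, 14 of 35 higher than both), and 0.62 after quantile normalization and 2.37 with the BioB and BioC controls. On the pit array, oxidative phosphorylation genes had a median of -0.39 (0th percentile), ribosomal protein genes one of -0.78 (0th) and citric acid cycle genes one of -0.64 (1.5th, but 4.75th after quantile normalization). In zymogenic minus pit values, the first 2 lists lay at the 98.4th and 99.96th percentile. Glycolysis genes, with a median of 1.02, lay at the 93.6th percentile. In zymogenic minus parietal values, the lists lay at the 13.5th (oxidative phosphorylation), 30.9th (citric acid cycle), 17.1th (fatty acid oxidation) and 48.9th (ribosomal proteins) percentile, and fatty acid oxidation lay at the 92.9th in parietal minus pit values, so that these did not stand apart there from other genes of like expression. The ribosomal list was at the 95.3rd percentile with the mean over all probe sets of a gene and at the 97.1st with transcript-specific ones.

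Genes of epithelial defence, a list of detoxifying and antioxidant enzymes and antibacterial proteins, had the highest median of the 31 lists on the parietal array. The median log2 ratio was 1.99 (1.14 to 2.77, 100th percentile), and 8 of 13 members were at least 2-fold above both. It was 1.54 after quantile normalization, 1.25 with 1 median and 2.87 with the BioB and BioC controls. Lypd8, a protein that keeps bacteria from the epithelium, stood at 4723 against 9.07 and 1049.6 on the zymogenic and pit arrays, and the glutathione transferase Gsta4 at 3165 against 20.0 and 908. The pit marker Gkn2 had the same order of arrays, at 7987 against 8.28 and 2723. The cells that gave these values on the parietal array are therefore not settled. On the zymogenic array the same list had a median of -2.02 (0.355th percentile, and 9.31th against the pit array alone).

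In all, 48 genes were at least 4-fold higher on the parietal array than on both others, 18 of them with both others at or below the floor, and 2, Ly6g6c and Nupr1, which were picked out after their values were seen and lay under the floor there, were at least 4-fold lower. The count depended on the scaling, with 21 after quantile normalization, 16 with 1 median and 434 with the BioB and BioC controls. It was 25 with the pseudocount, 27 with the mean over probe sets, 74 with the floor at the 90th percentile, 101 without the zymogenic array and 262 without the pit array. Of 13 such genes with a further probe set above the floor, 9 had one that was also at least 2-fold higher.

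The zymogenic array was compared with the others to find what sets enzyme-secreting cells apart. Chia1, an acidic chitinase of the gastric lumen, stood at 9916 against 232 on the parietal and 33.9 on the pit array, a 42.8-fold difference from the higher of the 2. Among genes also above the floor on another array, Furin, a proprotein convertase, followed at 948 (31.4-fold), then Acyp1, Scml4, Ppfia4, Slc25a17, Pgc at 21.1-fold, Trpm6, Ubxn11, Hc (complement component C5), Clvs1 and Dcaf17, the last at 15.9-fold. With both other arrays at or below the floor, the brightest were Bod1l (1493, at least 64.2-fold), Naa40, Vps13b, Hipk2, Cblif (at least 24.01-fold), the growth factor Tgfa (513, at least 22.1-fold), the endocrine granule protein Chga (453, at least 19.5-fold), Gm17750, Acad10, Zbtb43, Tmed6 and Gper1. None of these genes had a further probe set that was also 2-fold higher. Chia1, Furin, Pgc, Hc, Cblif, Chga, Gm17750 and Tmed6 have no further probe set. Of the rest, only Hipk2 had further ones above the floor, 2 in number, and its log2 ratio was -1.43 with transcript-specific probe sets. The further probe sets of the other genes were under the floor on every array and could not show a rise.

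Among genes above the floor on all 3 arrays, those lowest on the zymogenic array relative to both others were Lyzl4 (24.6 against at least 5144), the odorant receptor Olfr870, Cdc26, Tagln2 and the protease cathepsin E, Ctse (64.8 against 2391 and 2105). Of these, Tagln2 had a further probe set that was also 2-fold lower, the further ones of Cdc26 and Ctse were under the floor on every array, and Lyzl4 and Olfr870 have none. Genes shared by epithelia were lower there as a group, with a median log2 ratio of -1.91 (0.29th percentile, but 5.2th with transcript-specific probe sets and 3.22th against the pit array alone) and 5 of 8 at least 2-fold below both other arrays, while on the parietal array the median was 1.35 (98.9th percentile, but 69.4th against the pit array alone). Krt19, a keratin, stood at 3.53 against 2928 and 1322, and the adhesion protein Cdh1 at 21.5 against 211 and 298, where E-cadherin staining had been used to choose both pit and zymogenic cells.

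Genes of the endoplasmic reticulum had small positive medians on the zymogenic array, with intervals over members that span 0, but stood apart from matched lists. The list of translocation and N-glycosylation genes had a median log2 ratio of 0.56 (-0.11 to 0.82, 99.9th percentile), with Spcs3 (103 against 27.6 and 19.6) and Srpr of 23 at least 2-fold above both others. The list of chaperones and stress response genes had a median of 0.26 (-0.21 to 1.15, 99.7th percentile), with Ero1b, Herpud1, Hyou1 and Dnajc3 of 17 higher and Ero1a lower than both. These medians were -0.12 and -0.35 with the arrays scaled to the BioB and BioC controls, with percentiles of 100 and 99.6, and the chaperones lay at the 97.05th percentile after quantile normalization. Xbp1, a regulator of secretory cells, was at 539 against 263 and 103.

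Across all genes, 107 were at least 4-fold higher on the zymogenic array than on both others, 71 of them with both others at or below the floor, and 163 were at least 4-fold lower. Of 22 enriched genes with a further probe set above the floor, 5 had one that was 2-fold higher, namely Asns, Phgdh, Pla2g1b, Pnliprp2 and Ttr, which were picked out after their values were seen. The count was 35 with the mean over all probe sets of a gene and 192 with the floor at the 90th percentile.

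The pit array was compared with the other 2 for genes that set mucous cells of the surface region apart. Psapl1, a prosaposin-like protein, stood at 9552 against 353 on the parietal array, a 27.1-fold difference that a further probe set shared. Krt20, a keratin of differentiated gut epithelium, was at 657 (20.4-fold), followed, among genes also measured elsewhere, by Gng4, the galectin Lgals3 (511, 8.63-fold), Efhd2, Mxd1, Bnip3, Rep15, Wipf2, Pdlim1, Myh14 and the cell cycle inhibitor Cdkn1a (508, 4.99-fold). Where both other arrays were at or below the floor, Krt7 was brightest (897, at least 38.6-fold), before Cybrd1, an iron reductase (335, at least 14.4-fold), Bnip5, Ahnak2, Rnase4, Inpp5a, Car3, Tmem43, Fmo5, Pstpip1, Btg1 and Jakmip1. Among genes above the floor on all 3 arrays, the lowest relative to both others were Pla2g1b, Clps, Atp4b, Pvr and Ttr, from 15.1-fold to 7.47-fold lower. Pla2g1b, Clps and Ttr had a further probe set that was also 2-fold lower, and Atp4b has no other. The 1 further probe set of Pvr above the floor went the other way, at least 2-fold higher on the pit array than on both others.

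The joint list of immediate early and heat shock genes had a median log2 ratio of 0.82 on the pit array (0.19 to 1.46, 99.9th percentile). It was 0.41 with the mean over probe sets and 0.12 with the BioB and BioC controls, at percentiles of 99.7 and 99.8. Gadd45b, Jund, Ier3 and Fos of 13 were at least 2-fold above both other arrays, with Jund at 669.6 against 222 and 138. The heat shock genes Hspa1b and Hsph1 went the other way and were highest on the parietal array. Genes of mucin O-glycosylation had a median of 0.79 (-0.011 to 1.41, 98.1st percentile, but 93.8th without the zymogenic array, 97.4th with the floor at the 90th percentile and 96.7th with transcript-specific probe sets), and of 0.087 with the BioB and BioC controls, with Galnt10 of 11 higher than both others and Gcnt3, a branching enzyme of mucin glycans, at 459 against 264 and 3.12. In all, 37 genes were at least 4-fold higher on the pit array than on both others, 15 of them with both others at or below the floor, and 21 were at least 4-fold lower. The count was 56 with 1 median, 10 with the BioB and BioC controls, 17 with the mean over probe sets, 22 with the pseudocount, 23 with transcript-specific probe sets, 63 with the floor at the 90th percentile and 291 without the parietal array. Of 11 with a further probe set above the floor, 7 had one that was 2-fold higher.

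**Figure D2:**
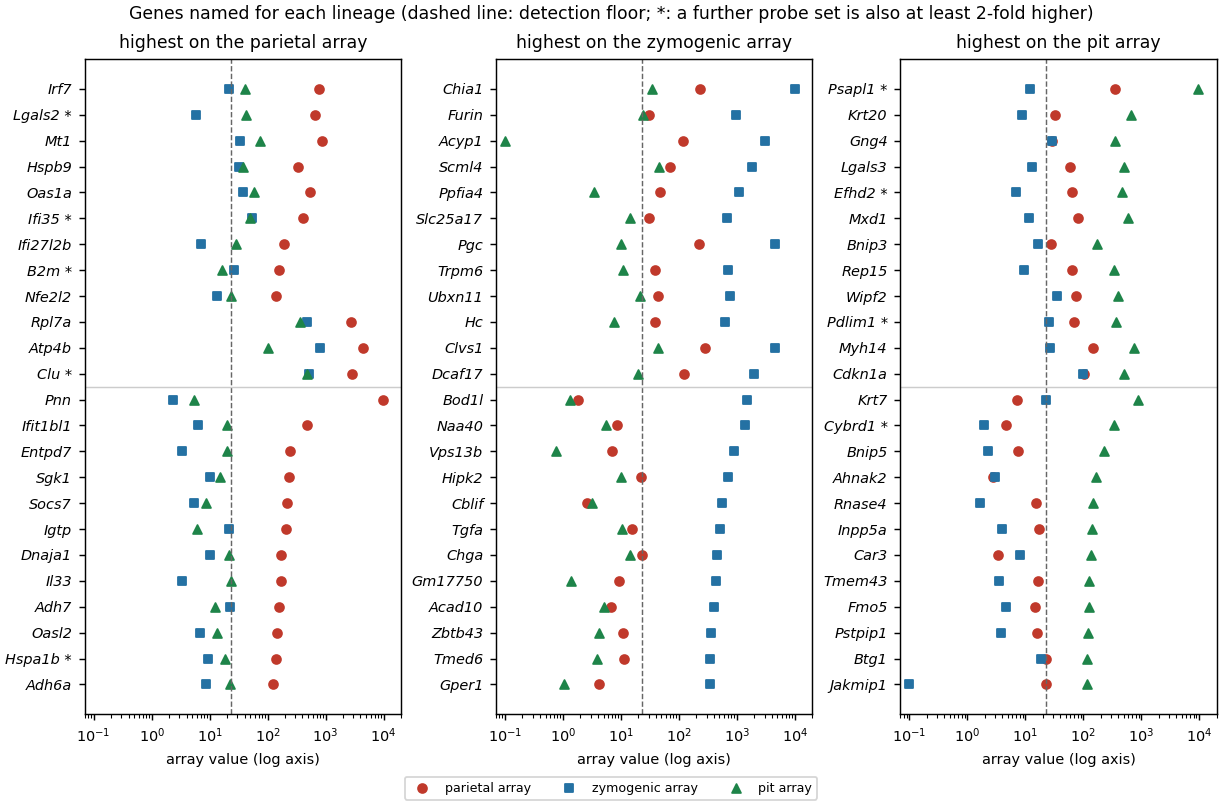
Values on the 3 arrays (log axis) of the genes named for each lineage, with genes measured on another array over the grey line and genes at or under the floor on both other arrays below it. The floor of 23.3 is dashed, values under 0.1 are drawn at 0.1, and a star marks genes with a further probe set at least 2-fold higher, which no gene of the zymogenic panel has. In that panel only Hipk2 has a further probe set above the floor.

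Parietal and pit cells, taken from the same units, were apart in fewer genes than either was from zymogenic cells. Of all genes, 141 were at least 4-fold apart, 101 higher in parietal and 40 higher in pit cells. The Spearman correlation across the 4138 genes was 0.647, where genes are not independent replicates. It was taken on unfloored values, so scatter under the floor can lower it. Over the 1984 genes above the floor on both arrays, the Pearson correlation of log2 values was 0.770. Among genes above the floor on both arrays, Atp4b (43.0-fold), Irf7, Lgals2, Smim38 (15.5-fold) and Pla2g1b (15.1-fold) were furthest towards parietal cells, and Psapl1 (27.1-fold), Krt20, Gng4, Lgals3 and Efhd2 towards pit cells. Genes under the floor on 1 of the arrays are not in that order, and Pnn, for example, was at least 420-fold higher on the parietal array and Krt7 at least 38.6-fold higher on the pit array. The parietal share of these genes, 71.6%, was 51.6% after quantile normalization, 38.7% with 1 median and 98.1% with the BioB and BioC controls, so the balance between the lineages depended on the scaling. With those controls 635 genes were apart, more than the 384 between zymogenic and pit cells. The number was 93 after quantile normalization, 79 with the pseudocount, 69 with the mean over probe sets, 73 with transcript-specific ones and 231 with the floor at the 90th percentile.

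Zymogenic and pit cells were 4-fold apart in 430 genes, 139 higher in zymogenic and 291 higher in pit cells. The Spearman correlation, again with values under the floor included, was 0.0718. Over the 1277 genes above the floor on both arrays, the Pearson correlation of log2 values was 0.446. Among genes above the floor on both, Chia1 (292-fold), Pla2g1b (239-fold), Clvs1, Ttr and Clps were furthest towards zymogenic cells, and Lyzl4 (209-fold), Olfr870, Hsd17b11, Cdc26 and Tagln2 towards pit cells. Among genes under it on 1 array, Pgc was at least 197.5-fold higher on the zymogenic array and Gkn1 at least 357-fold higher on the pit array. The number was 199 with the mean over probe sets, 279 with transcript-specific ones and 804 with the floor at the 90th percentile. The zymogenic share was 32.3%, and 44.9% after quantile normalization.

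Zymogenic and parietal cells were 4-fold apart in 379 genes, 117 higher in zymogenic and 262 higher in parietal cells. The Spearman correlation, with values under the floor included, was 0.253. Over the 1497 genes above the floor on both arrays, the Pearson correlation of log2 values was 0.581. Of the genes above the floor on both, Chia1 (42.8-fold), Furin, Acyp1, Scml4 and Ppfia4 were furthest towards zymogenic cells, and Lyzl4 (222-fold), Olfr870, the glutathione transferase Gsto1 (61.7-fold), Cdc26 and Pon2 towards parietal cells. Of those under it on 1 array, Bod1l was at least 64.2-fold higher on the zymogenic array and Gkn1 at least 451-fold higher on the parietal array. The number was 174 with the mean over probe sets, 239 with transcript-specific ones, 683 with the floor at the 90th percentile and 1093 with the BioB and BioC controls. The zymogenic share, 30.9%, was 54.1% after quantile normalization, 55.0% with 1 median and 6.95% with the BioB and BioC controls.

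Markers of other cell types were read as a check on the purity of the collections. Endocrine genes stood out on the zymogenic array, with a median log2 ratio of 1.79 over 5 of 20 above the floor (0.80 to 4.28, 99.9th percentile, and 0.68 with the floor at the 90th percentile), from Chga, Ghrl (298 against 7.43 and 29.2), Chgb, Sst and Hdc. Genes typical of the pancreatic acinar cell did too, with a median of 2.45 over 5 genes (-0.73 to 3.78, 99.96th percentile), but 0.14 (95.55th percentile of lists) with the floor at the 90th percentile and -0.18 with the BioB and BioC controls. Clps (colipase) was at 10451 against 2889 and 199, and Pnliprp2 and Pnliprp1 were also higher, but the proteases Prss2 and Ctrb1 were not. On the parietal array, mucous neck genes had a median of 1.42 over 2 genes (-0.15 to 2.99, 98.6th percentile, but 91.6th with the mean over all probe sets and 88.6th against the pit array alone), from Tff2 at 402 against 21.9 and 110. Leukocyte genes had a median of 0.16 on the zymogenic array (94.0th percentile), with Csf1r at 374 and Cd79a at 48.8, and fibroblast and smooth muscle genes one of 0.38 on the parietal array (85.8th percentile), from Col3a1 at 103 and Col1a2 at 125. On the pit array the latter list had a median of -0.27 (1.14th percentile, but 6.42th with 1 median and 25.4th with transcript-specific probe sets). Endothelial genes had 1 of 12 above the floor (Plvap), squamous forestomach genes 1 of 10 (Krt4), tuft cell genes 2 of 8 (Dclk1 at 87.3 on the zymogenic and Avil at 88.2 on the pit array), and erythrocyte genes 0 of the 3 that a probe set names. Intestinal genes had medians of 0.056, -0.067 and 0.14 on the parietal, zymogenic and pit arrays, with Apoa1 at 734 on the parietal array.

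**Figure D3:**
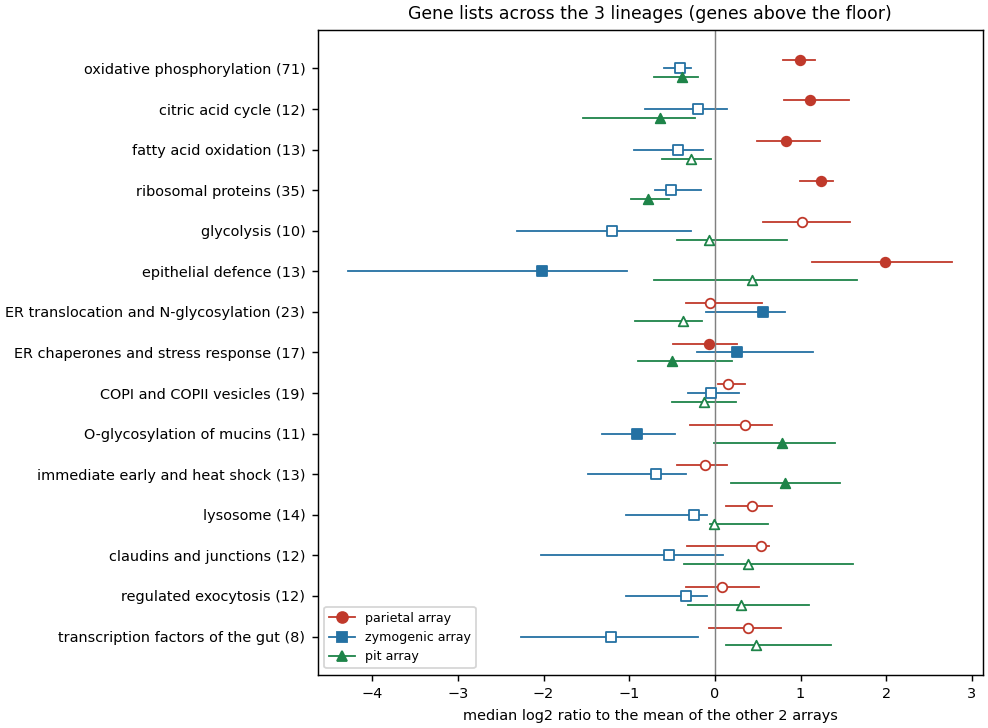
Median log2 ratio of each gene list on one array to the mean of the other 2, with the number of members above the floor in brackets and lines for the 95% bootstrap interval over members. Filled symbols lie outside the central 95% of matched random lists, as for oxidative phosphorylation and epithelial defence on the parietal array (0.99 and 1.99).

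The other function lists lay within the central 95% of matched random lists on every array. COPI and COPII vesicle genes had medians of 0.15, -0.043 and -0.12 on the parietal, zymogenic and pit arrays, with Tmed3 (125 against 39.1 and 34.7) highest on the zymogenic array. Regulated exocytosis genes had medians of 0.079, -0.33 and 0.31, with Syt7 highest on the zymogenic array and Stx3 and Rab27a on the pit array. Medians were 0.54, -0.53 and 0.39 for claudins and junctions, where Dsg2, Dsc2 and Pkp3 were highest on the pit array, and 0.43, -0.24 and -0.0077 for lysosomal genes. Gut transcription factors had 0.39, -1.21 and 0.48, with Ehf at 264 on the pit array and Sox21 at 177 on the parietal array. Secreted signals had -0.33, -0.078 and 0.38, led by Tgfa on the zymogenic array. Of 28 cell cycle genes 4 were above the floor on any array (Mki67, Cdc20, Rrm1 and Tpx2), with medians of 0.36, -0.27 and 0.14.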

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

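The predictions for the probe set test were written before its result was seen. Probe sets with no gene in the table were at least 4-fold higher than on both other arrays 4 times on the parietal array, 23 times on the zymogenic array and 6 times on the pit array, which is a signal in data that the comparisons did not use. The brightest of them on the zymogenic array read 3058 against at most 0.23 elsewhere. The control probe set for the middle of 18S ribosomal RNA read 97.6 on the parietal array and 239.9 on the zymogenic array, above the floor of 23.3, and 19.2 on the pit array.

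Many genes called higher on the zymogenic array rest on 1 probe set. If single probe sets did not follow their genes, under 50% of enriched genes with a further probe set above the floor should have one that is 2-fold higher, and the value was 22.7% (5 of 22) on the zymogenic array, which is consistent with that explanation. On the parietal array it was 69.2% (9 of 13) and on the pit array 63.6% (7 of 11), between the bounds set for either reading, so single probe sets cannot be told apart there from changes of the gene. Loss of 5′ ends in amplification may also silence some probe sets of a true transcript, and was not tested.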

How the results depend on the processing

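The scaling to the BioB and BioC controls and the settings that leave out an array were chosen after seeing the data. No paired analysis was possible because each lineage has 1 array. Of 565 values for named genes under alternatives, 301 moved by more than the scatter between probe sets and 1 reversed. The 10 list medians that lead a comparison had 96 values under alternatives, of which 21 moved out of their interval over members and 1 reversed. The 80 other list medians had 578 such values, of which 111 moved and 4 reversed. Of 32 list medians outside the central 95% of matched lists, 5 came to lie inside it with quantile normalization, 4 with 1 median, 5 with the BioB and BioC controls, 5 with the pseudocount, 6 with the 90th percentile floor, 7 with the mean over probe sets and 13 with transcript-specific probe sets, and of 6 each, 2 did without the pit array and 2 without the zymogenic array. With the 99th percentile floor all 16 that could still be taken did, such as oxidative phosphorylation (79.5th percentile) and ribosomal proteins (95.9th) on the parietal array and zymogenic markers (76.8th) on their own. The cause was not tested except where stated. Signal close to the floor limits most genes, since 4138 of 18194 exceeded it.

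With quantile normalization, the genes enriched in parietal cells numbered 21 and those apart between parietal and pit cells 93, and list medians were 0.93 for ER translocation (zymogenic), 0.53 for oxidative phosphorylation and 0.62 for ribosomal proteins (parietal). With 1 median, 16 genes were enriched in parietal and 56 in pit cells, and medians were -0.074 for parietal markers, 0.88 for ER translocation, 0.49 for oxidative phosphorylation and 0.64 for ribosomal proteins. The 99th percentile floor of 868 was set by the Olfr870 probe set and left 81 genes, with 4 (parietal), 5 (zymogenic) and 1 (pit) enriched and 5 (parietal and pit), 13 (zymogenic and pit) and 21 (zymogenic and parietal) apart. Its medians were 2.34 for parietal markers, 0.29 for pit markers, 0.41 for oxidative phosphorylation and 1.42 for ribosomal proteins. The 90th percentile floor admitted more genes, with 74, 192 and 63 enriched and 231, 804 and 683 apart in the same order, 0.68 for endocrine genes and 0.0078 for pancreatic acinar genes on the pit array, which reversed. With the floor as a pseudocount, 25 parietal and 22 pit genes were enriched and 79 were apart between parietal and pit cells.

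With the mean over all probe sets of a gene, 27, 35 and 17 genes were enriched and 69, 199 and 174 apart, with 0.75 for oxidative phosphorylation and 0.91 for ribosomal proteins. With transcript-specific probe sets, which left 2847 genes above the floor, 23 pit genes were enriched and 73, 279 and 239 genes apart, ribosomal proteins had 1.46, and Hipk2 reversed to -1.43. At 2-fold, 310, 286 and 239 genes were enriched and 762, 1199 and 1179 apart, and at 8-fold 11, 45 and 7 and 31, 176 and 142.

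Scaled to the BioB and BioC controls, 434 parietal and 10 pit genes were enriched, and 635 (parietal and pit) and 1093 (zymogenic and parietal) were apart, and 58 of 72 named genes moved. Medians were 0.87 for pit markers, 0.12 for immediate early genes (pit), 2.87 for epithelial defence, 2.17 for oxidative phosphorylation and 2.37 for ribosomal proteins (parietal). Those for pancreatic acinar genes (-0.18), ER translocation (-0.12) and ER chaperones (-0.35) on the zymogenic array and ER chaperones on the parietal array (0.94) reversed. Without the zymogenic array, 101 parietal genes were enriched and the pit marker median was 0.23. Without the pit array 262 parietal genes, and without the parietal array 291 pit genes, were enriched, since 1 comparison fewer had to be met.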

Other observations

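Of the tests in this part, that of a general rise of silent genes was chosen after its values were seen. The lists for the interferon test and for the further endocrine genes were drawn up after the genes that raised each question were seen, with those genes left out, and before their own values were. The bounds of the 6 tests of carry-over were written before their results, but the conditions that the highest ratio be measured, that the span hold without markers brighter on the other array and that no single marker carry it were added after.

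The 4 genes that follow were chosen after their values were seen, from those with a further probe set 2-fold higher on the zymogenic array, and stand for no group. Asns, asparagine synthetase, stood at 409.7 against at most 65.2, and Phgdh, the first enzyme of serine synthesis, at 163 against at most 4.25. Pla2g1b, a secreted phospholipase, read 10938 against 692 and 45.8, and Ttr, transthyretin, 2889 against 232 and 31.1.

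Interferon-response genes were tested as a group because Irf7, Oas1a, Ifi35, Igtp and Oasl2 were among the genes named for the parietal array. Of 55 further genes, 23 were above the floor, and their median log2 ratio on the parietal array was 1.25 (0.84 to 1.61), at the 100th percentile of matched lists, with 11 at least 2-fold higher than both other arrays. Ifit1 (105 against 12.1 and 4.82), Samd9l, Parp14 and Ifih1 were among them, while H2-D1 went the other way, at 21.3 against 141 on the zymogenic array. Trim25 (298 against 334) and Irf1 (44.9 against 52.2) were lower on the parietal than on the pit array. Oasl1 (178) and Ddx58 (24.6) were level on these arrays. A hypothesis is that the parietal collection had a stronger interferon response than the mean of the other collections. The list median was not taken for parietal minus pit values, so the pit collection of the same units was not tested alone. Partly different cells in the parietal and pit collections stay open. In parietal minus pit values, leukocyte genes had a median of 0.055 (65.1th percentile) and fibroblast and smooth muscle genes one of 0.38 (92.6th percentile). Csf1r was at least 4.75-fold, Laptm5 2.47-fold, Col1a2 4.91-fold and Col3a1 at least 4.45-fold higher. With 1 pool per lineage, a difference between pools stays open.

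Markers of 1 lineage appeared on the arrays of others, such as Gkn1 and Gkn2 on the parietal array. If carried-over cells with the profile of the collected ones were the whole source, all abundant markers should share 1 ratio. Yet the log2 ratio spanned 5.90 for pit markers on the parietal array (Gkn2 at 293% and Krt20 at 4.90% of their pit values). It spanned 5.26 for parietal markers on the zymogenic array (Atp4a at 122%, and Car2 at or under the floor and at most 3.18%). With any 1 marker left out, these spans were at least 3.08 and 2.90. Pit cells were collected at the apex, in a layer 2 to 3 cells thick, and parietal cells from the pit zone. Carried-over cells with another profile than the collected ones could give unequal ratios, and the spans and shares given here cannot exclude them. Pit markers on the zymogenic array spanned 6.65, from Psca at 28.1% to Gkn1 at most 0.28%, and even at the 21.4% of Vsig1, which like Psca is near the floor, Gkn1 would stand at 1780, Gkn2 at 584 and Muc5ac at 263, but they read 12.5, 8.28 and 14.5. The spans of 4.39 and 5.80 for zymogenic markers on the parietal and pit arrays rest on Xbp1, without which they were 1.02 and 0, and the 6.02 of parietal markers on the pit array runs from Slc12a2 at 150% to Atp4b at 2.32% and was 3.63 without Slc12a2 and Ezr, both brighter there than on the parietal array. The bounds set for the spans left these last 3 cases undecided. At the 2.32% of Atp4b, Car2, Ezr and Slc12a2 would read 17.0, 3.30 and 3.94 on the pit array, but they read 210, 171 and 255. For these 3 genes that argues against carry-over as the whole source. Atp4a and Clic6 lay under the floor there. For them, for Atp4b and for the zymogenic markers, carry-over as the whole source cannot be told apart from expression in several lineages. Partial carry-over stays open in all 6 cases.

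Endocrine genes on the zymogenic array, with Chga at 453, Ghrl at 298, Chgb at 80.3, Sst at 75.9 and Hdc at 40.4, none of which is on another list, may come from endocrine cells collected with the zymogenic cells, since E-cadherin staining with no GSII or DBA would not remove them. Of 25 further endocrine genes that a probe set names, 4 were above the floor, with Scgn at 208, Pcsk1n at 36.2 and Cplx2 at 30.5 on the zymogenic array alone but Ptprn2 at 5.28 there against 70.5 and 59.2, and their median log2 ratio of 0.52 (-1.47 to 3.16) lay at the 94.98th percentile of matched lists, which leaves the question open. A general rise of silent genes was set against this by the share of genes at least 4-fold higher, which was 2 of 20 for endocrine genes and 1 of 71 for receptor genes, a ratio of 7.10. That ratio passed the bound set against a general rise, but the exact binomial intervals, 1.23% to 31.7% and 0.0357% to 7.599%, overlap, a condition added after the ratio was seen. The receptor probe sets also set the floor, at their 95th percentile on the zymogenic array, so few of them could lie 4-fold above it. That percentile was 23.3 on the zymogenic, 11.2 on the parietal and 15.2 on the pit array, with medians of 3.54, 3.56 and 3.08. The ratio therefore cannot decide the question. The 2 readings cannot be told apart.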
